A study of Mycobacterium dioxanotrophicus with 2 samples.

How the data were processed

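RNA-seq was carried out on Mycobacterium dioxanotrophicus PH-06, a bacterium that can use the cyclic ether 1,4-dioxane as a source of carbon and energy. Per the labels' protocols, cells were harvested in exponential growth, partway through the use of the substrate, and were washed repeatedly in mineral medium before total RNA was extracted with a Qiagen column kit. Libraries were made with an Illumina mRNA-Seq kit, per the labels' protocols. The data hold 2 libraries, 1 from cells grown on dioxane at 500 mg per L and 1 from cells grown on glucose, and the series states that there was no replicate. The group of each library came from its source name. The growth protocol of the glucose library repeats the text given for dioxane, so the glucose concentration is not given in the sources used here. The growth phase and harvest point of the glucose cells rest on the same repeated text.

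The authors deposited, for each gene, a whole-number count of reads per library and a ratio of the 2 libraries. The aligner, the counting program, the genome build and the use of strand are not given in the sources used here, and neither is any step that removed ribosomal RNA. The deposited ratio is a fold change of dioxane over glucose. Recomputing it as each count divided by its library's total, with ribosomal RNA left in the total, gave the same values with a largest relative difference of 1.4e-15. The whole-genome table held 7811 genes named by locus tag and product, and 1 further row without a gene name, which held the column totals and was left out. The tables of the chromosome and of the 4 plasmids held the same counts for all 7811 genes. Locus numbers advanced in steps of 5 with no gap, so locus order served as gene order. No coordinates, gene lengths or sequences were used here, so gene length and GC content were not examined. Near-identical copies, such as those of the ribosomal RNA genes, may share reads, and the counting of such reads is not known. Without strand, reads of overlapping or antisense genes cannot be told apart.

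Counts were taken as deposited. Log2 ratios of dioxane over glucose were computed from CPM values with edgeR 4.0.16 in R 4.3.3, with a prior count of 1 and library sizes scaled by TMM, a method that trims the genes with the most extreme ratios and levels before it sets the scale. The TMM factors were 1.89 for dioxane and 0.529 for glucose. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. With 1 library per carbon source there is no spread between replicates, so no p-value was computed and a fixed size took its place. A gene was counted as higher or lower when its log2 ratio was at least 2 in size, which is 4-fold. No expression filter applied to that count, and genes named with a log2 ratio had at least 20 reads over both libraries, which 7659 genes had. Each ratio has an exact 95% Clopper-Pearson interval from the split of its reads between the libraries. Such intervals cover counting error only, not the variation between cultures or library preparations.

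The lists of genes and the rule for naming genes were fixed before the data were examined. There were 36 lists, matched by words in the product names. The rule named all members of the list for soluble di-iron monooxygenases and the 12 highest and 12 lowest log2 ratios. It further named up to 4 members of each list with the largest ratios in size, and the members of any run of 3 or more neighbours past 4-fold in 1 direction that held a gene of the first groups. The neighbouring monooxygenase genes of plasmid 3 and the further genes of the plasmid 3 region were chosen after their values were seen. So were further genes among those with the most reads, of named runs and of some lists. Each list's median log2 ratio was set against medians of 10000 random lists of the same size, drawn from non-members in the same 20 bins of mean expression. This percentile describes these 2 libraries and is not a test of the carbon source. Genes of an operon vary together, which random lists do not copy, so the percentiles overstate how far a list of operon genes stands apart. Chance alone would put 1.8 of the 36 lists outside the central 95%. Name matching caught products of other functions in 17 lists, 91 members in all, and the lists were repeated without them. That repeat was chosen after the data were seen. Runs of neighbouring genes were compared with 1000 shufflings of gene order.

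The procedure was tested on simulated data. Counts were drawn for 7811 genes from the real means and library sizes of dioxane and glucose, with 200 genes changed by known amounts. Of 50 genes changed 16-fold, 50 passed 4-fold, as did 47 of 50 changed 8-fold, 25 of 50 changed exactly 4-fold and 1 of 50 changed 2-fold. Of 7519 unchanged genes, 7 passed 4-fold, and 0 of the 7372 with at least 20 reads did. Of 200 simulated lists of unchanged genes, 9 fell outside the central 95% of random lists. The simulated counts held counting error only, and the simulated lists held genes drawn independently. These rates therefore do not cover variation between cultures or library preparations, or operon genes that vary together. The changed genes were few, with as many raised as lowered, whereas 3120 genes passed 2-fold in the real data. Error in the TMM scale is thus not covered either.

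Alternatives fixed beforehand were prior counts of 0.25 and 5, read minimums of 20 and 200, centring on the median, scaling to the total and to the upper quartile, and 2-fold and 8-fold sizes. The TMM scale was estimated anew at each read minimum. The fixed alternatives also covered the authors' deposited fold change, leaving out ribosomal and transfer RNA, leaving out mobile elements, chromosomal members of lists alone, unmatched random lists, and other definitions of a run. Relative log expression factors, scaling to the reads without ribosomal RNA, the plasmid 3 monooxygenase cluster, and the minimum of 200 reads with the main scale kept were added after the data were seen.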

Results

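Transcripts were counted in cells of Mycobacterium dioxanotrophicus PH-06 grown on 1,4-dioxane or on glucose, with 1 library for each carbon source. The comparison asks which genes differ in transcript level when the cyclic ether, rather than a sugar, feeds the cells. The dioxane library held 7211040 reads assigned to 7811 genes and the glucose library held 11478693. The genome is divided into a chromosome with 7320 genes and plasmids 1 to 4 with 146, 159, 110 and 76 genes. There were no replicates, so a difference below compares 2 libraries, and the variation between cultures is unknown.

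Ribosomal RNA made up 28.7% of the dioxane reads and 82.7% of the glucose reads, and the exact 95% binomial limits of each share round to the same value. Transfer RNA took 5.90% and 3.56%. After both were set aside, 4716987 reads of the dioxane library and 1578051 reads of the glucose library lay on the other 7719 genes, with a median of 140 and 67 reads per gene. The glucose library, although larger in total, was therefore the shallower one for these genes, mostly messenger RNA. Large-subunit 23S ribosomal RNA alone held 26.8% of the dioxane and 73.7% of the glucose reads. Small-subunit 16S ribosomal RNA held 1.5% and 8.41%. Of the 3 copies of the 16S gene, BTO20_RS24005 had 8 reads in each library, and how reads of near-identical copies were assigned is not known.

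**Figure D1:**
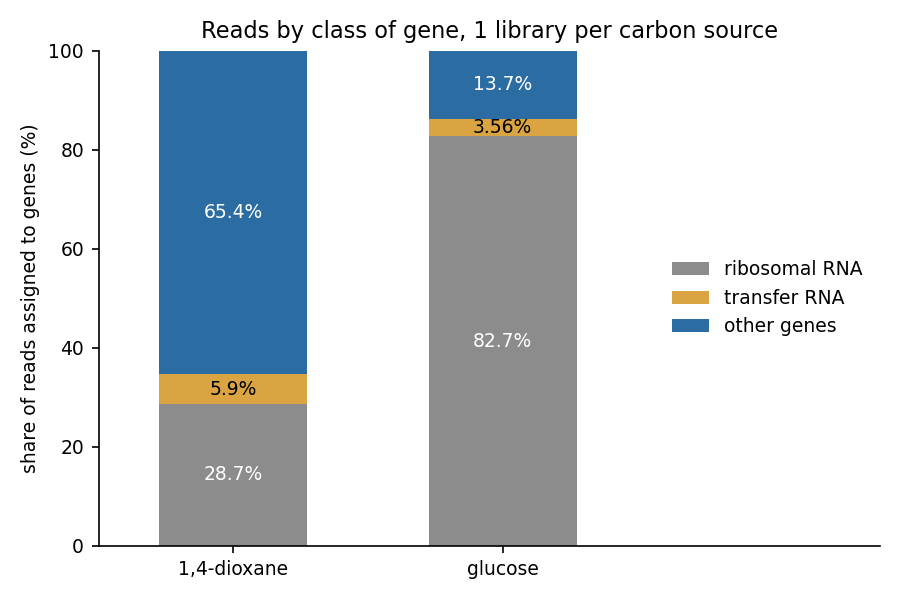
Share of reads assigned to genes, in percent, that fell on ribosomal RNA, transfer RNA and all other genes in the dioxane and the glucose library, 1 bar per library. Other genes held 65.4% of the dioxane reads and 13.7% of the glucose reads.

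Across all genes, 387 were at least 4-fold higher on dioxane and 608 at least 4-fold lower, and the median log2 ratio was -0.0079. Higher genes made up 38.9% of the 995 past 4-fold. This split depended on the scale. Among the 4270 genes with at least 200 reads on the same scale, 356 were higher and 358 lower, 49.9% of them higher. The median log2 ratio of these 4270 genes was 0.32. With the scale estimated anew for them, 251 were higher and 444 lower, 36.1% of them higher. With counts divided by total reads, ribosomal RNA included, 3329 genes were higher and 93 lower, 97.3% of them higher, and the median log2 ratio was 1.80. With ribosomal RNA taken out of the totals, 295 were higher and 740 lower, 28.5% of them higher, with a median of -0.21. Directions below are those on the TMM scale. With total scaling the medians of all 36 gene lists lay above 0, so 17 of them changed sign, and with ribosomal RNA out of the totals 6 did, all with a main median of 0.16 or less in size. In the authors' deposited table, which uses total reads, the median fold change was 3.56. Of the 995 genes past 4-fold in the main scaling, 977 had counting intervals that lay wholly beyond 2-fold. Genes 4-fold higher had a median of 930 dioxane and 69 glucose reads, and genes 4-fold lower had a median of 54 and 182.5 reads.

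The highest ratio among genes with at least 20 reads was that of DnaK (BTO20_RS32590), the Hsp70 chaperone that helps proteins fold. It had 40550 reads on dioxane and 594 on glucose, a log2 ratio of 4.92 with a 95% counting interval of 4.81 to 5.05. The chaperonin GroL (BTO20_RS04740), a subunit of the barrel in which proteins fold, comes after a hypothetical gene, BTO20_RS04735, in locus order. Their log2 ratios were 4.20 and 4.57. A transcriptional regulator (BTO20_RS07090) reached 4.62 and its neighbour, a hemin transporter (BTO20_RS07095), 4.10. A TetR family regulator (BTO20_RS14670) reached 4.53 within a run of 5 genes that also held an antibiotic ABC transporter permease (BTO20_RS14675, 3.94) and a multidrug transporter ATP-binding protein (BTO20_RS14680, 2.99). An anti-sigma regulatory factor (BTO20_RS03935, 4.23) stood between a response regulator (BTO20_RS03930, 3.73) and an anti-anti-sigma factor (BTO20_RS03940, 3.52). The remaining genes of the top 12 were a 4-carboxymuconolactone decarboxylase (BTO20_RS02405, 4.31), hypothetical genes BTO20_RS17525 (4.27) and BTO20_RS30090 (4.26), holo-ACP synthase (BTO20_RS11020, 4.04) and an acyl-CoA desaturase (BTO20_RS00445, 4.03).

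The lowest ratio was that of a hypothetical gene, BTO20_RS34895, with 95 reads on dioxane and 3383 on glucose. It was 78.8-fold lower on dioxane, a log2 ratio of -6.30 with an interval of -6.63 to -6.03. A gene named 5,10-methylene tetrahydromethanopterin reductase (BTO20_RS34070) followed at -5.59, then hypothetical genes BTO20_RS31720 (-5.55) and BTO20_RS31435 (-5.39) and an MFS transporter (BTO20_RS27040, -5.29). Among the next were an IS1380 family transposase (BTO20_RS09805, -5.16), an amine oxidase (BTO20_RS36290, -5.16) and AraC family regulators BTO20_RS34185 (-5.15) and BTO20_RS31175 (-5.11). A mycofactocin-dependent oxidoreductase (BTO20_RS10815, -5.09), hypothetical gene BTO20_RS11500 (-5.03) and a sulfate transporter subunit (BTO20_RS34830, -5.01) completed the lowest 12. Of these, BTO20_RS31435 was the only one in a run of neighbours past 4-fold.

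**Figure D2:**
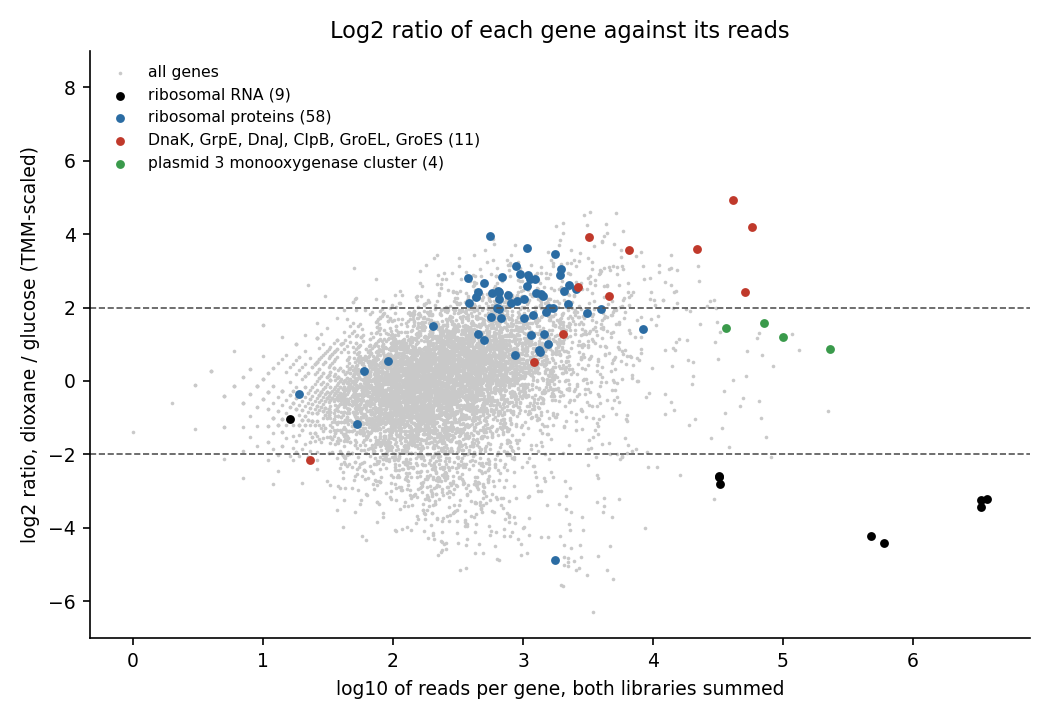
Log2 ratio of dioxane over glucose for each of 7811 genes (vertical axis, TMM-scaled) against the log10 of its reads summed over both libraries (horizontal axis); dashed lines mark 4-fold. Most of the 58 ribosomal protein genes lie above the centre of the cloud, DnaK tops the chaperones at 4.92, and 8 of the 9 ribosomal RNA genes lie below the lower line.

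Soluble di-iron monooxygenases insert oxygen into small hydrocarbons and ethers, and enzymes of this family start the breakdown of cyclic ethers. The list fixed for them matched 5 genes, and a check of the product names left 0 of the 5, so no median of this family is given. Of the 5 matched genes 0 passed 4-fold. On plasmid 3, a gene named methane monooxygenase/ammonia monooxygenase subunit A (BTO20_RS38400) had 334 and 71 reads and a log2 ratio of 1.06, with an interval of 0.69 to 1.46. Phenol 2-monooxygenase (BTO20_RS24130) lay at 0.14 with an interval of -0.28 to 0.59. The other members were polyprenyl-phenol hydroxylase-like genes at 0.82 (BTO20_RS29315), -0.22 (BTO20_RS32565, interval -0.64 to 0.19) and -1.54 (BTO20_RS16350).

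A block of oxygenase genes with many reads on plasmid 3 carries only the bare names monooxygenase (BTO20_RS38210, BTO20_RS38215 and BTO20_RS38220) and oxidoreductase (BTO20_RS38225). The list missed this block, which was chosen after its values were seen. Together these 4 neighbours held 7.68% of all reads outside ribosomal and transfer RNA on dioxane and 4.83% on glucose. By reads, not corrected for gene length, BTO20_RS38210 ranked 1 among such genes on dioxane, with 185042, and 2 on glucose, with 45413. Log2 ratios along the block were 0.86 (interval 0.84 to 0.87), 1.19 (1.16 to 1.21), 1.44 (1.40 to 1.48) and 1.59 (1.55 to 1.62), or 1.81-fold to 3.0-fold, and 0 of the 4 genes passed 4-fold. The next gene, a plasmid-borne chaperonin GroEL (BTO20_RS38230), stood at 2.44, and the hypothetical gene after it (BTO20_RS38235) at 3.71 from 841 and 28 reads. In the authors' deposited table the 4 genes had fold changes of 6.49 to 10.7, on the scale where the median gene stood at 3.56. Scaled to reads without ribosomal RNA, their log2 ratios ranged from 0.65 to 1.38. The median of the block, 1.31, lay at percentile 81.2 of random lists matched on expression and at percentile 98.0 of unmatched lists.

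**Figure D3:**
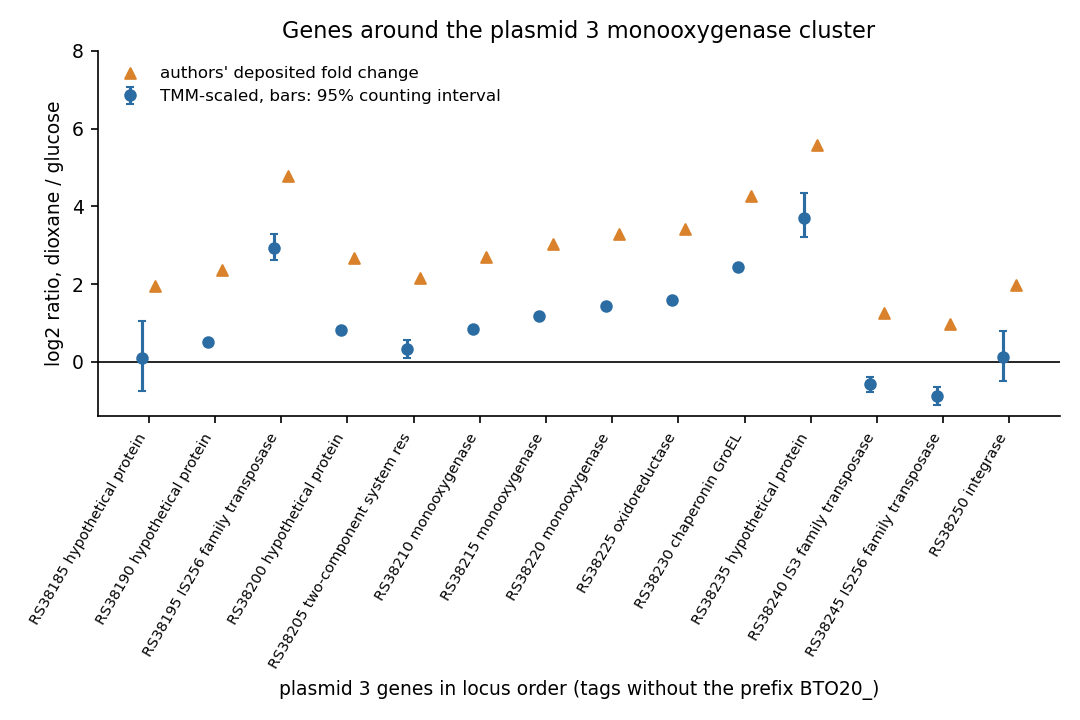
Log2 ratio of dioxane over glucose (vertical axis) of plasmid 3 genes in locus order around the monooxygenase block, TMM-scaled with 95% counting intervals (circles) and as the authors' deposited fold change (triangles). The TMM-scaled ratio climbs from 0.86 at BTO20_RS38210 to 3.71 at BTO20_RS38235, and the deposited values lie above it by a near-constant step.

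Genes of protein folding were higher on dioxane. All 5 chaperonin genes had ratios above 0 and 4 passed 4-fold, with a median of 2.56 at percentile 99.7 of matched lists. Besides GroL and the plasmid 3 copy these were GroEL (BTO20_RS27640, 3.56) and its partner GroES (BTO20_RS27645, 2.56). The plasmid 2 copy, BTO20_RS37395, stood at 0.51. Of 14 heat shock and protease genes, 6 were 4-fold higher and 1 was 4-fold lower, with a median of 1.45 at percentile 99.7. DnaK formed a run with its co-factors GrpE (BTO20_RS32585, 3.91) and DnaJ (BTO20_RS32580, 2.32) and a MerR family regulator (BTO20_RS32575). The disaggregase ClpB (BTO20_RS32525) reached 3.60. Near-identical chaperonin copies may share reads.

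Ribosomal protein genes lay higher on dioxane as a group. Of 58, 33 were at least 4-fold higher, 1 was 4-fold lower and 24 lay between, with a median log2 ratio of 2.16 (95% interval over members 1.96 to 2.39) above all 10000 matched random medians. The highest were L30 (BTO20_RS28430, 3.96), L33 (BTO20_RS07110, 3.62) and L21 (BTO20_RS12020, 3.47). The exception, an L28 gene (BTO20_RS04280), had 124 reads on dioxane and 1643 on glucose, a log2 ratio of -4.88. The longest run of neighbours past 4-fold held 11 ribosomal protein genes, from S17 (BTO20_RS28605, 2.43) to S10 (BTO20_RS28655, 2.61). Translation factors and tRNA ligases had a median of 1.03 over 34 genes at percentile 99.9, with 3 higher and 1 lower past 4-fold. Initiation factor IF-3 (BTO20_RS14535, 2.80), elongation factor P (BTO20_RS18935, 2.48) and elongation factor G (BTO20_RS28780, 2.35) were the 3. The gene below -2 in this list, GreAB (BTO20_RS02915, -2.05), acts in transcription rather than translation. Ribosomal and transfer RNA went the other way, with a median of -0.92 over 96 matched genes, 20 of them 4-fold lower, below all matched random medians.

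Energy genes were split. The list of respiratory chain and ATP synthase genes had a median of 1.05 over 35 genes at percentile 99.95, with 11 genes 4-fold higher and 0 lower. ATP synthase, which makes ATP from the proton gradient, had 6 of 8 subunits 4-fold higher and a median of 3.08. Subunit A (BTO20_RS09910) was highest at 3.69, and the beta subunit (BTO20_RS09940) lowest at 1.09. The 14 NADH dehydrogenase subunits, which feed electrons from NADH into the chain, had a median of -0.24 and lay between -1.04 and 0.71. A cytochrome c oxidase subunit I gene (BTO20_RS08915) reached 3.48 in a run with a ferredoxin (BTO20_RS08920, 3.25) and a cyanoglobin (BTO20_RS08925, 3.83). Nitrogen assimilation genes had a median of -0.47 over 48 genes at percentile 1.33, yet 4 were 4-fold higher. Among these were the respiratory nitrate reductase subunits beta (BTO20_RS08830, 3.41) and gamma (BTO20_RS08840, 3.29), which serve respiration rather than assimilation. Glutamate dehydrogenase (BTO20_RS02735, -4.24) and urease subunit alpha (BTO20_RS17005, -3.77) were among the 6 genes 4-fold lower. Without chance matches of names the median was -0.64 over 44 genes at percentile 0.34. The 25 members with at least 200 reads had a median of 0.31 on the main scale, where that of all such genes was 0.32. When the scale was estimated anew these medians were 0.04 and 0.05.

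**Figure D4:**
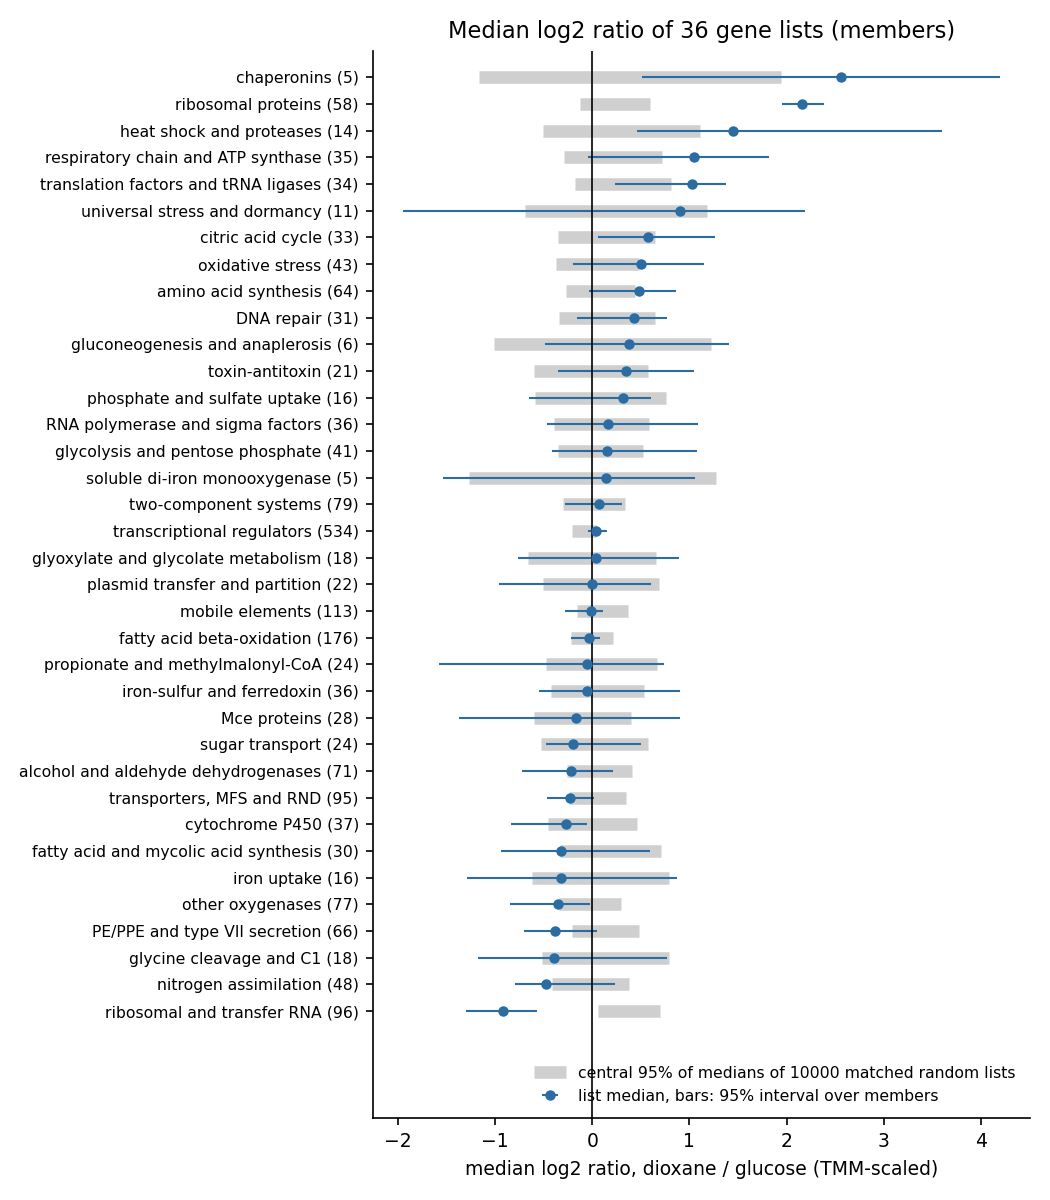
Median log2 ratio of dioxane over glucose (horizontal axis, TMM-scaled) of 36 gene lists, with the number of members in brackets; bars are 95% intervals of the median over members, and grey bands hold the central 95% of medians of 10000 random lists matched on expression. Chaperonins (2.56) and ribosomal proteins (2.16) stand highest and ribosomal and transfer RNA (-0.92) lowest.

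No list of central carbon metabolism lay outside the central 95% of its matched random lists. Glycolysis and pentose phosphate genes had a median of 0.15 over 41 genes, gluconeogenesis and anaplerosis 0.38 over 6, and sugar transport -0.20 over 24. The glucose transporter subunit IIBC of the phosphotransferase system (BTO20_RS24755), which takes up and phosphorylates sugars, stood at 1.54. The only sugar transport gene past 4-fold, a sugar ABC transporter substrate-binding protein (BTO20_RS12645), stood at -2.85. Of the glycolysis and pentose phosphate genes 2 were 4-fold higher and 2 lower. These were triose-phosphate isomerase (BTO20_RS18630, 2.38), phosphoglycerate kinase (BTO20_RS18635, 2.03), a 6-phosphofructokinase (BTO20_RS03415, -2.275) and a transketolase (BTO20_RS18745, -3.23). The citric acid cycle had a median of 0.57 over 33 genes at percentile 95.2, or 0.43 over 27 genes at percentile 83.4 without chance matches of names. Of the 33 genes 4 were 4-fold higher, among them aconitate hydratase (BTO20_RS12855, 2.53) and 2-oxoglutarate ferredoxin oxidoreductase subunit alpha (BTO20_RS11940, 2.41). The 2 genes 4-fold lower were a 4-aminobutyrate transaminase (BTO20_RS08980, -4.11) and a succinate dehydrogenase subunit (BTO20_RS21835, -2.30). The name check left 1 of these 2. For glyoxylate, an intermediate that enters metabolism through glyoxylate carboligase, the list matched 18 genes with a median of 0.04. The 14 genes left by the name check had the same median. The carboligase gene of the chromosome (BTO20_RS17465) stood at -2.27 and that of plasmid 1 (BTO20_RS37320) at 0.61. Alcohol and aldehyde dehydrogenases had a median of -0.22 over 71 genes, with 4 higher and 7 lower past 4-fold. The ends of that list were alcohol dehydrogenase BTO20_RS23920 at 3.35 and aldehyde dehydrogenase BTO20_RS35150 at -4.30. The list of other oxygenases had a median of -0.36 over 77 genes at percentile 1.63, with 0 higher and 8 lower past 4-fold. It held the 19 genes named only monooxygenase, and so 3 genes of the plasmid 3 block. The lowest was 3-(2,3-dihydroxyphenyl)propionate dioxygenase (BTO20_RS10420, -4.44). Cytochrome P450 genes had a median of -0.27 over 37 genes.

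In the main setting lipid and envelope lists had medians below 0, where the median of all genes was -0.0079. Fatty acid beta-oxidation had a median of -0.036 over 176 genes, propionate and methylmalonyl-CoA genes -0.051 over 24 (-0.19 over the 21 left by the name check), Mce proteins -0.17 over 28, and fatty acid and mycolic acid synthesis -0.32 over 30. The last list held genes at both ends, with 3-oxoacyl-ACP synthase (BTO20_RS11015) at 3.12 and an acetyl-CoA carboxylase subunit (BTO20_RS24155) at -4.02. The lists of beta-oxidation, propionate, Mce and fatty acid synthesis lay within the central 95% of their matched random lists. Their percentiles were 34.0, 28.3, 38.0 and 2.87. PE/PPE proteins and type VII secretion, an export system of mycobacteria, had a median of -0.38 over 66 genes at percentile 0.19, with 4 higher and 8 lower past 4-fold. A secretion membrane protein EccD (BTO20_RS35965) stood at -3.23, while the secreted protein EsxB (BTO20_RS35980) nearby stood at 2.60. MFS and RND transporters had a median of -0.23 over 95 genes. Some of these directions turned among members with at least 200 reads and the scale estimated anew, to 0.41 over 15 Mce genes, 0.29 over 16 propionate genes and 0.01 over 96 beta-oxidation genes. Relative to all genes, beta-oxidation did not turn, at -0.028 in the main setting and -0.037 at 200 reads.

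Of the lists not yet given, 3 lay above the central 95% of their matched random lists. Oxidative stress genes had a median of 0.50 over 43 genes at percentile 98.1, with 1 higher and 3 lower past 4-fold. Without chance matches of names the median became 0.45 over 38 genes at percentile 96.4. Amino acid synthesis had a median of 0.48 over 64 genes at percentile 98.6, with 6 higher and 8 lower past 4-fold, and 0.64 over the 57 genes left by the name check. Universal stress and dormancy genes had a median of 0.90 over 11 genes, within the central 95%, with 3 higher and 1 lower past 4-fold. Stress proteins BTO20_RS30235 and BTO20_RS30240 stood at 2.20 and 2.19, and stress protein BTO20_RS07415 at -4.13. The pattern for transcriptional regulators matched 534 genes, 21 of them by a stretch of words such as tetrahydrofolate, with a median of 0.04 at percentile 97.9. The other 513 had a median of 0.05 at percentile 99.2. Past 4-fold, 18 of the 534 were higher and 36 lower, and the mean log2 ratio of the 534 was -0.093. Medians of the other lists were 0.16 for RNA polymerase and sigma factors, 0.06 for two-component systems, 0.43 for DNA repair, 0.35 for toxin-antitoxin genes (0.11 over the 17 left by the name check) and 0.31 for phosphate and sulfate uptake. They were -0.33 for iron uptake, -0.052 for iron-sulfur and ferredoxin genes, -0.40 for glycine cleavage and C1 genes, -0.011 for mobile elements and -0.0043 for plasmid transfer and partition, the last 2 at -0.044 and -0.048 after the name check. In all, 8 lists lay above percentile 97.5 and 4 below percentile 2.5, against 1.8 in total by chance. After the name check, with random lists drawn anew, these counts were 7 and 5, as oxidative stress moved inside and the unchanged list of MFS and RND transporters went from percentile 2.64 to 2.49.

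The replicons differed less than these groups. Median log2 ratios were 0.46 for plasmid 3 (95% interval over genes 0.31 to 0.61), 0.35 for plasmid 1 (0.16 to 0.50), 0.11 for plasmid 2 (0.025 to 0.29), 0.04 for plasmid 4 (-0.31 to 0.31) and -0.036 for the chromosome (-0.070 to -0.0016). On plasmid 3, 5 genes were 4-fold higher and 1 lower, and on plasmid 2, 0 were higher and 3 lower. The chromosome held 378 of the higher and 595 of the lower genes. Plasmid 3 took 11.9% of the reads outside ribosomal and transfer RNA on dioxane and 7.91% on glucose. Scaled to reads without ribosomal RNA the medians of plasmids 2 and 4 were -0.077 and -0.17. The median of all genes was -0.21 on that scale, so both stayed above it and the turn in sign came from the shared shift. With a minimum of 200 reads the plasmid medians relative to all genes dropped to 0.27 for plasmid 3 and 0.12 for plasmid 1, and turned to -0.078 for plasmid 2 and -0.35 for plasmid 4.

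In the main setting, genes higher on dioxane lay side by side more often than genes lower on dioxane. There were 33 runs of at least 3 neighbours 4-fold higher, with 130 genes, and 17 runs 4-fold lower, with 53 genes. With 1 gap allowed in a run the numbers were 37 and 33, and for 2 or more neighbours 81 and 78, so the contrast in number depended on how a run was defined. Shuffled gene order gave means of 0.87 and 3.42 runs, and at most 5 and 10. Runs of higher genes held ribosomal proteins, ATP synthase subunits, the DnaK genes, the cytochrome b and c genes from BTO20_RS13515 (2.00) to BTO20_RS13530 (2.66), and a meromycolate acyl carrier protein (BTO20_RS13165, 2.61), which serves mycolic acid synthesis. Runs of lower genes held 4 neighbours at most, among them a sensor histidine kinase (BTO20_RS31840, -3.21) with its response regulator (BTO20_RS31835, -3.03), and taurine dioxygenase (BTO20_RS05740, -4.07). Of the runs of lower genes, ribosomal RNA operons made up those that begin at BTO20_RS09965 and BTO20_RS14695. Outside ribosomal and transfer RNA, 58.4% of the higher genes and 27.9% of the lower genes had an adjacent gene past 4-fold in the same direction.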

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

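With 1 library per carbon source, no alternative could test replicates. No paired analysis was possible because each group has 1 library, numbered in accession order only. All-gene medians shifted by 1.80 on the log2 scale with total scaling, by 1.84 with the authors' deposited fold change, by -0.10 with the upper quartile and by -0.20 with reads without ribosomal RNA, so lists, replicons and single genes were compared relative to that median. Scalings apply 1 factor to every gene and so hardly touch such relative values; they are left out of the counts that follow. Of the rest, 193 of 196 alternative values of list medians and 21 of 25 of replicon medians moved by less than the margin of their 95% intervals. For named genes 91 of 481 moved by more and 0 turned a ratio whose counting interval excludes 0. Prior counts and read minimums reuse the same counts and could hardly turn a large ratio, so the 0 says little for such genes. Margins were wide for some lists, with an interval of -1.37 to 0.90 for Mce proteins, so a list median could turn sign within its margin. The choices that were added, named in the methods, came after the data were seen.

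Total scaling gave 3329 higher and 93 lower, and the authors' deposited fold change gave 3417 and 98, by construction of the shared total. A 2-fold size gave 1466 and 1654, and an 8-fold size gave 89 and 234. A minimum of 200 reads gave 251 higher and 444 lower with the TMM scale estimated anew, and 356 and 358 with the main scale kept. The same minimum moved medians relative to all genes to 0.12, -0.078, 0.27 and -0.35 for plasmids 1 to 4, to 1.92 for ribosomal proteins, to -0.26 for mobile elements and to -1.34 for ribosomal and transfer RNA. The cause was not tested. In sign, 7 list medians turned at 200 reads with the scale estimated anew: 0.08 for alcohol and aldehyde dehydrogenases, 0.29 for propionate, 0.01 for beta-oxidation, 0.41 for Mce, 0.59 for iron-sulfur, 0.04 for nitrogen and 0.07 for glycine cleavage. With the main scale kept 11 turned. Relative to all genes 7 turned, but not the same 7. Beta-oxidation (-0.037) and nitrogen (-0.011) did not turn on that measure, while regulators (-0.044) and plasmid transfer (-0.14) did. With unmatched random lists the citric acid cycle reached percentile 99.2 and universal stress genes percentile 98.5, while regulators dropped to percentile 82.2. The plasmid 3 block's median log2 ratio was 3.15 from the authors' deposited fold change, 1.11 scaled to reads without ribosomal RNA and 1.04 at 200 reads. Runs higher and lower numbered 157 and 139 at 2-fold, 6 and 2 at 8-fold, 81 and 78 for 2 or more neighbours and 6 and 0 for 5 or more. With 1 gap allowed there were 37 and 33. Depth limits the glucose library most, with a median of 67 reads per gene outside ribosomal and transfer RNA.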

Other observations

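The weighing tests on ribosomal RNA were chosen after the result was seen, and the others were written beforehand. The naming rule gave BTO20_RS11655, BTO20_RS08315, BTO20_RS30235 and BTO20_RS30240 of the next paragraph, and its other genes were chosen after their values were seen.

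Several genes with many reads were shared by both carbon sources. Of the 15 genes with the most reads outside ribosomal and transfer RNA, 11 were the same in both libraries. Reads were not corrected for gene length, so such ranks favour long genes in both libraries. The gene named for ethyl tert-butyl ether degradation, EthD (BTO20_RS00490), ranked 11 in both, with 52689 and 10318 reads and a log2 ratio of 1.18. Tyramine oxidase (BTO20_RS29620), which oxidises amines, stood at 1.30, and a betaine-aldehyde dehydrogenase nearby (BTO20_RS29630) at 1.34. Hypothetical genes BTO20_RS37435 and BTO20_RS37440 of plasmid 2 held 106789 and 62914 dioxane reads and stood at 0.83 and 0.40. The gene with the most glucose reads outside ribosomal and transfer RNA, the hypothetical gene BTO20_RS03690 with 97912 reads, stood at -0.82. A site-specific integrase (BTO20_RS11655) ranked 14 on glucose with 7660 reads and 662 on dioxane with 1074 reads. A second hemin transporter gene (BTO20_RS01600) stood at 3.43 with 13168 dioxane reads, next to a fatty acid-binding-like protein (BTO20_RS01595, 3.78) and a hydrolase (BTO20_RS01590, 3.72). A sensor histidine kinase and a response regulator (BTO20_RS08315 and BTO20_RS08310) stood at 3.05 and 3.02 beside a nitroreductase (BTO20_RS08305, 2.04), and universal stress proteins BTO20_RS30235 and BTO20_RS30240 lay in a run with a cyclase (BTO20_RS30230, 2.98).

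Ribosomal RNA took 28.7% of the dioxane reads against 82.7% of the glucose reads. Fewer ribosomes in the dioxane cells, as the whole cause, would lower 16S and 23S ribosomal RNA alike. The log2 ratio of the 16S copies differed from that of the 23S copies by -1.06, but with 1 library per carbon source there is no spread between cultures to set this against, so fewer ribosomes stay open. More complete removal of ribosomal RNA from the dioxane library remains a candidate explanation. Transfer RNAs, which such a removal would leave in place, lay above 23S ribosomal RNA by 2.37. Removal and carbon source cannot be told apart here, because each carbon source has 1 library.

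Genes lower on dioxane often stood alone among neighbours, with a median neighbour log2 ratio of -0.68 against 1.43 for genes higher on dioxane. A lone peak was defined as a gene with over 8 times the reads of both neighbours, and the glucose library held 180 and the dioxane library 87. Lower depth of messenger reads on glucose did not account for the larger number of lone peaks there. The dioxane library thinned to 1578051 reads held 79 to 94 lone peaks in 100 draws, on average 47.9% of the glucose number. Neighbours of the lower genes were not compared at equal depth, so a part of depth in their median of -0.68 is not decided. Reads piled up on single genes of the glucose library may contribute, as 13.7% of the genes 4-fold lower were lone peaks there, but this lies between the bounds set beforehand for and against it. Of the genes 4-fold higher, 3.68% were lone peaks of the dioxane library. Genes picked for an excess of reads in 1 library favour peaks of that library, so the 1.26% among genes within 2-fold decides nothing. Whether such peaks are transcripts specific to glucose or a trait of 1 library cannot be told apart without a further library.

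Ribosomal protein genes lay higher on dioxane while ribosomal RNA lay lower. A glucose library whose reads spread more evenly over all genes would raise the ratio of any gene abundant on dioxane. Lists matched to the ribosomal proteins on dioxane count had medians centred at 0.74, with percentile 97.5 at 1.06. The ribosomal protein median of 2.16 lay above that limit and above the centre by 1.42. No biological explanation was tested, so carbon source, growth rate and harvest stay open as causes. Library preparation stays open too, because each carbon source has 1 library.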
